A study of Mus musculus with 192 samples.

How the data were processed

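The samples were 192 single cells from the bone marrow of C57BL/6 mice aged 8 to 16 weeks, per the labels' protocols. Marrow was enriched for cKit on magnetic beads, stained with antibodies and sorted 1 cell per well into 384-well plates, per the labels' protocols. The sorter's signal for each antibody and the scatter of each cell are given in the labels in arbitrary units. The labels' protocols name an antibody against CD48, of which the labels give no signal, and do not name 1 against CD11b, of which they do. They introduce the list of antibodies as a selection.

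Libraries were made with an adapted CEL-seq2 protocol, which primes on the poly(A) tail, with 96 primers that carry a cell index of 8 bases and a molecular identifier (UMI) of 6 random bases, per the labels' protocols. ERCC spike-in RNA was added. First strands were pooled before the second strand was made. The deposited values are raw UMI counts per gene and cell, with no normalization. The aligner, the counting tool and the rule for collapsing UMIs are not given in the sources used here. Per the submitters' processing notes the genome build was GRCh38, a human build, while every gene in the counts carries a mouse Ensembl identifier; the build actually used is therefore not known. Coordinates and symbols were taken from GENCODE M21 on GRCm38 by identifier.

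The counts held 20764 genes and 71 spike-ins. Of the genes, 20528 had a symbol in the annotation, and the 236 without one held 0.473% of the UMIs. No mitochondrially encoded gene was among them, so the mitochondrial share could not be used as a filter. The largest count of a gene in a cell was 3223, of the 4096 sequences that 6 bases allow. Counts that near the limit can be lowered by UMI collisions, and they enter the total UMIs of a cell. No correction for UMI collisions was made. Gm42418, which overlaps a ribosomal RNA repeat, held 6.455% of the gene UMIs, Camk1d 1.561% and Gm26384 0.358%.

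The first index in a cell's title defined its library pool. Cells were kept from 20% of their pool's median gene UMIs, which left 191. Doublets were not called, as the cells were sorted singly. For each surface protein the cells of each pool were ranked by the label value before the filter, and the 32 highest, 32 middle and 32 lowest formed the upper, middle and lower class. CD127-high cells had a signal above 2000, a level set from the labels alone. In each pool, the stem gate held cells with CD150 among the 24 highest and CD135 below the median, the intermediate gate cells with CD150 not among the 24 highest and CD135 below the median, and the CD135-high gate cells with CD135 and not CD150 among the 24 highest. These gates follow ranks, not the sort regions of the study.

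UMIs were summed over the cells of a class and divided by all gene UMIs of that class, spike-ins left out, to give counts per 1000000 (CPM). A ratio of classes has an exact conditional binomial 95% interval, a sum an exact Poisson interval and a share of cells an exact Clopper-Pearson interval. All describe counting error in these cells. Since no animal is named, no test across samples was possible. A gene with no UMI on 1 side was set at its bound from a floor of 3 UMIs. To compare shares of cells with a UMI, each cell was thinned to 12147 UMIs, the 10th percentile, which left out 19 of the 191 cells.

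Gene lists, classes, filters, comparisons and most alternatives were fixed before the data were examined. There were 22 lists with 378 genes; the ones described, and those of which single members are named, were chosen after their values and alternatives were seen. A list's value is the median log2 ratio of its members with at least 10 UMIs in the classes compared, set against 10000 random lists of equal size matched on expression in 20 bins. Members are counted as higher or lower by the sign of their ratio. The interval of a median comes from 200 Poisson redraws of the counts, with the same floor as the median; that floor was set after the data were seen. Genes held by single cells are those with over 20% of their UMIs in 1 cell.

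Named genes followed a rule also fixed beforehand. They had at least 50 UMIs over the classes compared, the same sign in both pools, no cell with over 20% of the UMIs, and a symbol that is not a predicted model, a pseudogene or a ribosomal protein. From these, the 12 genes per direction (CD135, CD150, CD127) or 6 (the others) whose interval lay farthest from 0 were named. Dach1, the genes of the 7 proteins and up to 4 members with the most UMIs of a described list were added. Satb1 in the CD135 classes, the sum of Y-linked genes, the genes compared between pools or in individual cells, the pool ratios without 1 cell and the cluster value without CD127-high cells were chosen after their values were seen.

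For clustering, counts were scaled to 10000 per cell and log-transformed, and the 1000 most variable genes went through 10 principal components, 15 neighbours and Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2). Dach1, the genes of the measured proteins, the S-phase, G2/M, sex-linked and immediate early lists, ribosomal proteins and spike-ins were left out. A cluster was named from markers fixed beforehand. The scoring was set after the data were seen: at least 3 markers with 10 UMIs and a log2 ratio of 1 or more. Genes with over 20% of their UMIs in 1 cell were then left out of naming, because markers from 1 cell had named a cluster.

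The ratio and its interval were tested on simulated counts drawn from the real totals, with 200 of the genes changed. For CD135, over 7232 genes, a simulated 2-fold change was recovered at a median log2 of 0.97 and a 4-fold change at 2.01. The intervals held the true ratio for 96.1% of unchanged genes, 98% of those changed 2-fold and 94% of those changed 4-fold. The simulated counts were Poisson draws with the same mean share of a gene in every cell of a class. They held no variation from cell to cell, so this coverage bears on counting error only. For the 14 CD127-high cells, over 8714 genes, 77% of the intervals of genes changed 2-fold lay above 0. The pass criterion on coverage was reworded after 1 set of 100 genes gave 93%.

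Alternatives gave each cell equal weight, dropped or tightened the cell filter, scaled by median ratios, thinned the cells, split at the median, ranked over both pools, took each pool alone, left out the CD127-high or the CD150-richest cells, raised the CD127 threshold to 5000, left out each CD127-high cell in turn, changed the minimum for list members and changed the clustering. Totals without Gm42418, Camk1d and Gm26384 were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.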

Results

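The data were UMI counts from 192 single bone marrow cells of C57BL/6 mice, which the labels describe as LSK (Lin-negative, Sca-1-positive, cKit-positive) progenitors, in 2 library pools of 96 cells. For each cell the labels gave the antibody signals of CD135, CD150, CD127, Sca-1, cKit, CD16/32 and CD11b, and forward and side scatter. The labels name no animal, so the cells together were treated as 1 biological sample. Every value below describes these cells, with no test and no p-value. The 95% intervals cover counting error only, not variation from cell to cell or differences between animals.

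The counts held 3705550 gene UMIs. The 191 cells kept had a median of 17715 gene UMIs (3927 to 49372) and 4910 detected genes. Pool 1 held 1934940 gene UMIs with a median of 17866 per cell, and the kept cells of pool 2 held 1769902 with a median of 17404. The cell left out had 708 gene UMIs, 569 detected genes and 41.3% of its UMIs in spike-ins.

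Does Dach1, which the series title links to lymphoid priming, differ with the CD135 (FLT3) level on the cell surface? Dach1 (ENSMUSG00000055639, chromosome 14, 97786853 to 98169765 on the minus strand of GRCm38) encodes a nuclear transcriptional regulator. It stood at 196.5 CPM (UMIs per 1000000 gene UMIs; 95% Poisson interval 173 to 222) in the 63 CD135 lower cells and 127 (108 to 148.8) in the 64 middle cells. In the 64 CD135 upper cells it stood at 34.97 (25.2 to 47.3). The upper cells therefore had 5.62-fold less Dach1 than the lower cells (4.04 to 7.99), a log2 ratio of -2.49 (-3.00 to -2.01) from 42 against 251 UMIs. Both pools had the same order. Pool 1 went from 232 in the lower cells through 175.97 to 54.3 in the upper cells, and pool 2 from 154.6 through 77.4 to 13.9. Dach1 was lower in pool 2 than in pool 1 in all 3 CD135 classes. The classes were ranked within each pool, and the median CD135 signal was 684.7 in pool 2 and 478.2 in pool 1.

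At least 1 Dach1 UMI was seen in 79.4% of the lower cells (exact Clopper-Pearson interval 67.3 to 88.5), 67.2% of the middle cells and 31.3% of the upper cells (20.2 to 44.1). After every cell was thinned to 12147 UMIs the shares were 69.5%, 63.2% and 25%. Thinning left out 4 lower, 7 middle and 8 upper cells with fewer UMIs.

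**Figure D1:**
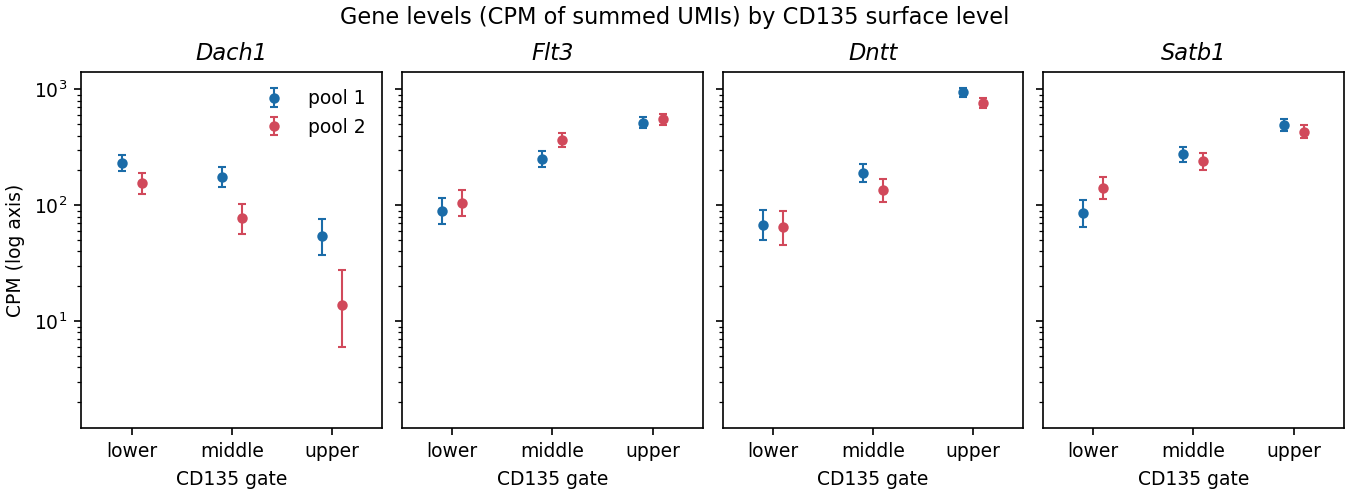
CPM of Dach1, Flt3, Dntt and Satb1 (log axis) in the CD135 lower, middle and upper cells of each library pool, with exact 95% Poisson intervals. Dach1 goes down from 232 to 54.3 in pool 1 and from 154.6 to 13.9 in pool 2, while the other genes go up in both pools.

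Which other genes separated the CD135 upper from the lower cells? Of the 12 genes chosen on the higher side, 6 were on the lymphoid priming list. Dntt, the terminal transferase of antigen receptor assembly, stood at 855 CPM in the upper cells against 66.5 in the lower cells (log2 3.68, 3.36 to 4.02). Ighm, the IgM heavy chain, had a log2 ratio of 4.34 (589 against 31 UMIs), and Ccr9, a homing receptor of thymus-seeding cells, 3.78 (6.09 in pool 1, 2.79 in pool 2). Flt3 itself, which encodes CD135, had 2.46 (2.18 to 2.75). Satb1 stood at 464.5 CPM in the upper, 258 in the middle and 111 in the lower cells.

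The other genes chosen on the higher side, some of them on the same list, had from 2 to 29 UMIs in the lower cells. Wfdc17 had 117 UMIs against 2 (log2 5.96, 4.07 to 9.02) and Cmah 68 against 2 (5.18, 3.27 to 8.25). The RNA helicase gene Ddx4 had a log2 ratio of 4.24, the actin regulator gene Evl 4.13, and the semaphorin gene Sema3d and the transporter gene Slc35d3 3.66 each (Sema3d 5.14 in pool 1 and 3.12 in pool 2, Slc35d3 5.31 and 3.004). Il12a, the p35 subunit of interleukin-12, had 3.06, and the NADPH oxidase gene Ncf1 had 2.98. Among the lymphoid priming genes with the most UMIs, Mef2c had a log2 ratio of 1.22 and Bcl11a 0.45. The 21 measured lymphoid priming genes had a median of 2.46, with 19 higher and 2 lower. That median lay above all 10000 random lists of matched expression and was 2.52 in pool 1 and 1.99 in pool 2. Flt3, the gene of the gating protein, is on this list and was itself the member at the median. Without it the median stayed within its counting interval (1.96 to 2.61).

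The genes lower in the CD135 upper cells included genes of the stem, megakaryocyte and erythroid programmes. The vesicular monoamine transporter gene Slc18a2 had 2 UMIs in the upper cells and 140 in the lower cells (log2 -6.04, -9.10 to -4.16). Pcdh7 had 1 against 53 (-5.64, -10.97 to -3.10) and Sdsl 2 against 51 (-4.58, -7.67 to -2.66). The transferrin receptor gene Tfr2 had a log2 ratio of -3.89, Pdzk1ip1 -3.50, Csgalnact1 -3.29, the haem-pathway gene Blvrb -3.27 and the TGF-beta co-receptor gene Tgfbr3 -3.13. Apoe had -2.89, the mucin gene Muc13 -2.66 and the transcription factor gene Gata2 -2.66. Dach1 was itself among the 12 genes of this side.

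All 17 measured erythroid genes were lower, with a median of -3.57. Of these, 10 had over 20% of their UMIs in a single cell, and the others had a median of -1.97. Car2 had -0.99 and Zfpm1, which encodes the GATA1 cofactor FOG1, -1.47, while for Tfrc the interval of its ratio of -0.25 spanned 0 (-0.72 to 0.21). Of 13 megakaryocyte genes 12 were lower (median -1.84). The thrombin receptor gene F2r had -1.32, Fli1 differed little (-0.38, -0.81 to 0.05), and Plek was the 1 gene higher (1.03). Of 17 stem cell genes 15 were lower, with a median of -1.06 (-0.60 in pool 1, -1.87 in pool 2). Angpt1 had -1.10, Meis1 -0.44, Txnip -0.25 and Hlf -0.10 (-0.26 to 0.05).

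Granulocyte-monocyte genes had no common direction, with a median of 0.18 (-0.43 in pool 1, 0.66 in pool 2). S-phase genes had a median of -0.07. G2/M genes were lower (median -0.74, 22 of 24 lower), with a median of -0.47 without the 16 held by single cells. MHC class II genes were higher (median 2.10, pool 1 0.24 and pool 2 2.08), as were the 9 measured dendritic genes (2.10), a list that shares members with them. Cd74 had a log2 ratio of 4.13 (1.79 in pool 1, 4.93 in pool 2), H2-Ab1 2.25 (0.23 and 3.06) and H2-Aa 2.10, but single cells held 63.5%, 52.8% and 55.7% of their UMIs. H2-DMa, with no such cell, had 0.62. Without the genes held by single cells the class II median was 0.21 and the dendritic median 0.61.

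**Figure D2:**
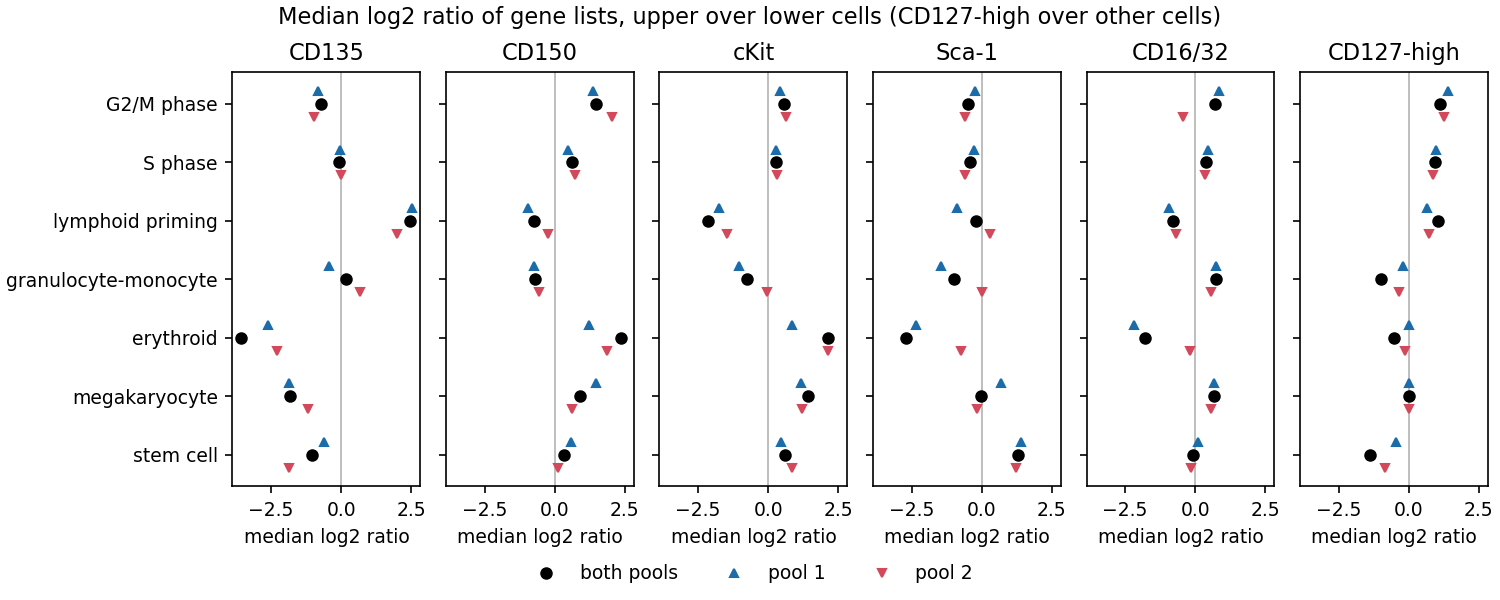
Median log2 ratio of 7 gene lists (horizontal axis, log2) in 6 comparisons, for both pools (circles), pool 1 (upward triangles) and pool 2 (downward triangles); genes without a UMI on 1 side are set at their bound from 3 UMIs. Lymphoid priming genes lie at 2.46 for CD135 and -2.14 for cKit, and G2/M genes at 1.48 for CD150.

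Did the antibody signals and the mRNA of the same proteins go together in the same cells? Il7r, which encodes CD127, had 48 UMIs in the 14 CD127-high cells and 2 in the 177 others (log2 8.07, 6.14 to 11.16). It was seen in 9 of the 14 cells and in 2 of the 177. Ly6a, the Sca-1 gene, had a log2 ratio of 3.22 (2.41 to 4.14) between Sca-1 upper and lower cells. Slamf1, the CD150 gene, had 14 against 1 UMIs (3.46, 0.75 to 8.87). Kit had 0.77 (0.59 to 0.97) across the cKit classes. For CD16/32, Fcgr3 had 18 against 2 UMIs (2.91, 0.85 to 6.06), and the interval of Fcgr2b spanned 0 (1.32, -0.21 to 3.14). Their sum had 1.98 (0.78 to 3.40). Itgam, which encodes CD11b, did not differ detectably between the CD11b upper and lower cells (-0.13, -0.90 to 0.65).

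What set the cells with most CD150, a marker conventionally used for stem cells within LSK, apart from those with least? Genes of dividing cells and of the erythro-megakaryocytic side were higher, while the lists of the stem side were divided. Apoe had a log2 ratio of 2.33 (1.84 to 2.87), Tnfaip2 2.66, Mns1 2.64, Tgfbr3 2.29, Slc18a2 1.82 (2.65 in pool 1, 0.61 in pool 2) and Vamp5 1.65. The kinetochore gene Knl1 had 2.12, the centromere gene Cenpm 2.29 (4.83 in pool 1, 0.91 in pool 2), the DNA repair gene Brca2 1.76 and the topoisomerase gene Top2a 1.47 (1.20 to 1.76). The histone genes Hist1h2ai and Hist1h2ab had 1.5 and 1.46, with 0.72 and 0.62 in pool 1 and 2.76 and 2.84 in pool 2. These histone genes share most of their sequence, and their counts were within 1 UMI of each other in 82 of the 94 cells with a UMI, so they count as 1 signal. Dach1 was higher in the CD150 upper cells (0.91, 0.57 to 1.26; 0.62 in pool 1, 1.496 in pool 2). Of the 63 CD150 upper cells 15 were also CD135 upper cells, against 26 of the 64 CD150 lower cells. The Dach1 and lymphoid differences by CD150 are therefore not separate from those by CD135.

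Lymphoid and other genes were lower in the CD150 upper cells. Ncf1 had -1.43, Ighm -1.13, the chromatin organiser gene Satb1 -1.06, Flt3 -0.89 (-1.11 to -0.67) and Dntt -0.47. Ahnak had -2.11 and the transcriptional regulator gene Mn1 -2.05. Rbm47 had -1.51, Brwd3 -1.41, Abr -1.26, Rasa4 -1.25, the fatty acid elongase gene Elovl6 -1.19 and Lztfl1 -1.12. The intervals of Bcl11a (-0.12, -0.29 to 0.05) and Mef2c (-0.18, -0.39 to 0.04) spanned 0. The lymphoid priming median was -0.75 (20 of 22 lower; -0.97 in pool 1, -0.25 in pool 2), the granulocyte-monocyte median -0.69 and the class II median -1.51, or -0.26 without the class II genes held by single cells.

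All 24 G2/M genes were higher in the CD150 upper cells, with a median of 1.48 (1.33 to 1.80; pool 1 1.37, pool 2 2.02). Mki67 had 1.38 (0.65 in pool 1, 2.89 in pool 2), Cdk1 1.5 (1.07 in pool 1, 2.87 in pool 2) and Kif20b 1.26. Of the 24 genes, 16 had over 20% of their UMIs in 1 cell, and the others had a median of 1.43. The same list had a median of 1.73 between the CD11b upper and lower cells, or 0.92 without the 16 genes held by single cells there. The S-phase median was 0.61 (21 of 24 higher): Mcm3 had 0.71 and Pcna 0.58, while Mcm7 (-0.08, -0.31 to 0.15) and Mcm6 (-0.02, -0.26 to 0.22) did not differ detectably. Megakaryocyte genes had a median of 0.90 and stem cell genes 0.34 (16 of 19 higher, with 0.57 in pool 1 and 0.10 in pool 2). Hox and stem transcription factor genes had -0.14 (-0.21 to 0.08, 12 of 21 lower). Quiescence genes had -0.26 (-0.49 to -0.12, 12 of 12 lower). The erythroid median of 2.35 rested in part on single cells and was 0.71 without the 7 genes they held.

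How did the 14 cells with a CD127 signal above 2000 differ from the other 177? They had more Dntt, at 1508 against 251 CPM (log2 2.59, 2.42 to 2.75). Summed over the group, they had more of the genes of DNA replication and mitosis. UMIs of Mki67 and Top2a lay mostly in cells 1, 2, 5 and 8 by falling CD127 signal. These held 13, 38, 50 and 50 of Mki67 and 36, 57, 72 and 73 of Top2a. No other CD127-high cell held more than 1 of Mki67 or 8 of Top2a. For these genes the higher sum therefore does not describe those other cells. Whether the other genes of mitosis lay in the same cells was not tested. The 14 cells also had more forward scatter, with a median of 151000 against 135000, and 11 of the 14 lay in its upper class. Whether cell size goes with the cell-cycle genes in these 14 cells was not tested. Pclaf, which encodes a PCNA-binding factor, had 3.19 (2.85 to 3.52), the kinesin gene Kif15 2.72, cyclin E2 (Ccne2) 2.69, Top2a 2.28, Mki67 2.17 with UMIs in 6 of the 14 cells, and Hist1h2ai and Hist1h2ab 2.09 and 2.08, or 1.38 and 1.40 without the eighth cell. Cmah had 3.22, the p21 gene Cdkn1a 3.07, the tropomyosin gene Tpm4 2.58 and Arpp21 2.43. Dach1 was lower, with 6 UMIs against 443 (19.8 against 130 CPM, log2 -2.72, -4.17 to -1.59), and was seen in 3 of the 14 cells against 110 of the 177. The tenth of the 14 cells by falling CD127 signal held 4 of the 6 Dach1 UMIs, and leaving it out gave a log2 ratio of -4.25. The sum of the 4 Y-linked genes was lower as well (36 against 908 UMIs, -1.17, -1.69 to -0.69), with a UMI in 13 of the 14 cells.

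Genes of stem cells and of the granulocyte-monocyte side were lower in the CD127-high cells. Gata2 had 1 UMI against 389 (log2 -5.12, -10.43 to -2.63) and Csgalnact1 1 against 220 (-4.30, -9.61 to -1.80), both UMIs in the tenth cell. Without that cell neither had a UMI, and the bounds from 3 UMIs were -3.47 and -2.65. Zfp281, Slc16a11 and the cathepsin G gene Ctsg had none. They were 5.53-fold, 3.60-fold and 3.57-fold lower at a floor of 3 UMIs over the 14 cells. The lower limits of their exact intervals were 4.46-fold, 2.88-fold and 2.86-fold. Muc13 had -3.20, the serpin gene Serpina3g -3.17, Apoe -2.88, Hlf -2.27 (-4.86 in pool 1, -1.55 in pool 2), the carbonic anhydrase gene Car2 -2.14 (-3.65 and -1.51) and Lmo2 -1.96. Single cells held back some of these differences: without the tenth cell Muc13 had -4.46 and Hlf -3.11, without the third Serpina3g had -4.09, and without the seventh Apoe had -3.84. Among the other stem cell genes with the most UMIs, Angpt1 had -1.71, Meis1 -1.45 and Ifitm1 -1.38 (-2.93 in pool 1, -0.81 in pool 2, -2.02 without the tenth cell). The erythroid median was -0.51 (15 of 17 lower), with 0 in pool 1 and -0.15 in pool 2, and -1.40 without the 9 genes held by single cells. Members without a UMI on 1 side are set at a bound from 3 UMIs that cannot pass 0. The pools hold 5 and 9 of the CD127-high cells, so list medians of these cells within a pool lean towards 0 by construction. The stem cell median was -1.38 (18 of 19 lower; -0.45 and -0.87 within the pools), and all 21 Hox and stem transcription factor genes were lower (median -0.84), among them Myb at -0.40 and Etv6 at -0.23 (-0.56 to 0.09).

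All 23 lymphoid priming genes had ratios above 0 in the CD127-high cells (median 1.03; 0.66 and 0.73 within the pools, 0.68 without the 4 genes held by single cells), among them Mef2c at 0.45 and Bcl11a at 0.33 (0.04 without the eighth cell), while the interval of Flt3 spanned 0 (0.11, -0.21 to 0.40). The S-phase median was 0.93 (23 of 24 higher), with Pcna at 0.94, Mcm6 at 0.96, Mcm7 at 0.77 and Mcm3 at 0.18 (-0.26 to 0.59). The G2/M median was 1.12, and 10 of those genes had over 20% of their UMIs in 1 cell. The granulocyte-monocyte median was -0.97 (-0.22 and -0.36 within the pools): Prtn3 had -2.26, Mpo -1.11 and Calr -0.51, while Plac8 was higher (0.79). Immediate early genes had a median of 0.99, from 0.01 in pool 1 and 1.16 in pool 2, and of 0.13 without the eighth cell. B-lineage genes had 5.38 and T, ILC and NK genes 2.16, but 7 of 9 and 6 of 11 of these genes were held by single cells. Without the second cell the B-lineage median was 0, and without the third the T, ILC and NK median was 0.92.

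Against the 55 CD135 upper cells without high CD127, the 9 CD127-high cells with CD135 above 1000 had a lymphoid priming median of 0.28, a stem cell median of -1.17 and a G2/M median of 2.07. In the last list 13 of 17 genes were held by single cells, and the others had a median of 1.09. Leaving out the fifth CD127-high cell brought the G2/M median to 0.93. Immediate early genes had a median of 1.45 (10 of 11 higher), but 0.22 without the eighth cell. Interferon genes had -1.30 (11 of 12 lower; -0.25 in pool 1, -0.74 in pool 2), and the 4 Y-linked genes, all lower, had -1.31 (-0.57 and -0.92). Il7r had 41 UMIs against 1 (log2 7.63, 5.07 to 12.97). Dach1 had 1 against 41 (-3.09, -8.43 to -0.53), the 1 UMI in the fifth cell. Without that cell the bound from 3 UMIs was -1.18, and pool 2 alone, with 0 against 8 UMIs, gave no difference at that floor.

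How did the levels of the sorting markers cKit and Sca-1 divide the cells? Lymphoid genes were lower in the cKit upper cells. Dntt had a log2 ratio of -3.72 (-4.06 to -3.40), Ighm -3.52, Flt3 -1.47, Mef2c -0.68 and Bcl11a -0.43, and the lymphoid priming median was -2.14 (21 of 23 lower), and -1.07 without the CD127-high cells. Among the lower genes outside that list were Cmah (-4.41), Arpp21 (-3.94), Evl (-3.72) and Emp1 (-3.26). The genes higher with cKit were Tgfbr3 (2.93), Sdsl (2.51), Tnfaip2 (2.31), Zfpm1 (1.99), Serpina3g (1.97, with 2.64 in pool 1 and 0.98 in pool 2) and Muc13 (1.89, 1.48 to 2.32). Dach1 was higher too (1.68, 1.27 to 2.10), with 1.09 in pool 1 and 3.55 in pool 2. Megakaryocyte genes had a median of 1.43, with F2r at 1.43, Fli1 at 0.37 (-0.07 to 0.81) and Plek at -0.11 (-0.45 to 0.23). The erythroid median was 2.15 (1.13 without genes held by single cells), the stem cell median 0.61 and the immediate early median -1.19 (-0.72 without such genes). Of the 14 CD127-high cells, 12 lay in the cKit lower class and none in the upper class. Of the 63 cKit lower cells 43 were also CD135 upper cells, against 2 of the 64 cKit upper cells. The lymphoid and Dach1 differences by cKit are therefore not separate from those by CD135.

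The Sca-1 upper cells had more of the stem cell programme. Besides Ly6a, they had more Procr (3.67, 2.36 to 5.34), which encodes the endothelial protein C receptor, and more Myof (2.90), Iigp1 (2.82), Mecom (2.16) and Hlf (1.91, 1.74 to 2.09). Ifitm1 had 1.49, Meis1 0.85 and Angpt1 0.72. The stem cell median was 1.29 (16 of 17 higher; 1.38 and 1.22 in the pools) and the Hox and stem transcription factor median 0.47. Myeloid genes were lower: Rab44 had -2.95, the myeloperoxidase gene Mpo -2.18, the transcription factor gene Irf8 -2.33 (-5.24 in pool 1, -1.81 in pool 2) and the mast cell protease gene Cpa3 -2.13. Blvrb had -2.69 and Cmah -2.60 (-4.83 in pool 1, -1.25 in pool 2). The granulocyte-monocyte median was -0.98 (-1.46 in pool 1, 0.00 in pool 2), or -0.56 without the 7 genes held by single cells. The erythroid median of -2.69 was -0.17 without the genes held by single cells. Dach1 did not differ detectably between Sca-1 classes (-0.03, -0.40 to 0.34). The 64 Sca-1 upper cells held 23 CD135 upper and 3 CD127-high cells, and the 63 lower cells 16 and 10. This value is therefore not separate from the differences by CD135 and CD127.

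Did CD16/32 (Fc gamma receptors) grade the cells towards the granulocyte-monocyte side? In the CD16/32 upper cells Mpo had a log2 ratio of 2.34 (2.04 to 2.65), Ctsg 2.89, Rab44 2.70 and the hexokinase gene Hk3 1.81. The proteinase 3 gene Prtn3 had 1.58 (2.36 in pool 1, 0.73 in pool 2). Itga2b, which encodes CD41, had 3.29. Calr had 0.78 and Plac8 0.46, and the granulocyte-monocyte median was 0.74 (17 of 21 higher). Lymphoid genes were lower, with Dntt at -2.38 and Ighm at -1.86. The 64 CD16/32 lower cells held 32 CD135 upper and 10 CD127-high cells, and the 63 upper cells 14 and 1. This difference is therefore not separate from those by CD135 and CD127. Other lower genes were Cmah at 3 against 68 UMIs (-4.76, -7.08 to -3.16) and Pygm at -2.48 (-4.58 in pool 1, -1.71 in pool 2). Emp1 had -2.47 and Rgl1 -2.43. The lymphoid priming median was -0.81 and the S-phase median 0.37. The erythroid median of -1.78 was -0.16 without genes held by single cells. The Dach1 ratio was 0.65 (0.32 to 0.99) but had opposite signs in the pools, 1.04 and -0.078.

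How did gates after the conventional CD150 and CD135 division of LSK cells compare? In the 33 cells of the stem gate (CD150 among the 24 highest of a pool, CD135 below the median) Dach1 stood at 244.9 CPM (212 to 282). The 62 cells with neither high CD150 nor CD135 above the median had 135 (114 to 158), and the 40 CD135-high cells without high CD150 had 32.4 (20.7 to 48.2). The log2 ratio of stem over CD135-high cells was 2.92 (2.30 to 3.60), from 193 against 24 UMIs. The pools had 258, 197 and 41.8 in pool 1 and 229, 69.2 and 19.3 in pool 2.

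Stem gate cells also had more Slc18a2 (98 against 2 UMIs, log2 5.53, 3.64 to 8.59), Tfr2 (55 against 2, 4.69, 2.77 to 7.77), Apoe (3.10), Csgalnact1 (3.10; 4.14 in pool 1, 1.83 in pool 2) and Gata2 (2.90). They had less Ncf1 (3 against 124, -5.46, -7.75 to -3.88), Wfdc17 (3 against 83, -4.88, -7.19 to -3.28) and Slc35d3 (3 against 59, -4.39, -6.70 to -2.77). Ighm had -4.69, Dntt -4.34 and Satb1 -3.51. The stem cell median was 1.24 (0.45 over members with at least 50 UMIs), the megakaryocyte median 1.87 and the erythroid median 3.18 (1.37 without genes held by single cells). The lymphoid priming median was -2.43 and the granulocyte-monocyte median -1.53 (-0.44 without genes held by single cells).

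Cells with more forward scatter held more RNA. In pool 1 the median was 28083.5 gene UMIs in the 32 upper cells against 15600 in the 32 lower cells, and in pool 2 it was 19901.5 against 14622.5. Over both pools the ratio of medians was 1.46, and for side scatter it was 1.20. The spike-in share went the other way, from 4.59% in the lower to 2.43% in the upper forward scatter cells of pool 1.

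Clustering by expression, with Dach1, the genes of the measured proteins and the cell-cycle lists left out, gave 7 clusters. Dach1 was highest in the 46 stem-like cells, at 250 CPM (216 to 289). It stood at 91.5 in 39 granulocyte-monocyte-like cells and 39.01 (18.7 to 71.7) in 10 erythroid-like cells. The granulocyte-monocyte-like cluster also held 8 of the 14 CD127-high cells and 27 Il7r UMIs, so it was mixed; its 31 other cells had 111 CPM of Dach1 (86.9 to 140). The lymphoid-primed-like clusters had the highest CD135 medians. That of 21 cells had a CD135 median of 1569 and 76.5 CPM of Dach1 (49.5 to 113), and that of 19 cells had 1705 and 9.18 (1.89 to 26.8). Their sum over the stem-like cells had a Dach1 log2 ratio of -2.55 (-3.17 to -1.97). The 2 unnamed clusters of 28 cells each had 141 and 92.0. The first of them held the most G2/M and S-phase genes of the 7 clusters, at 2514 and 4962 CPM. The second had 263 and 1913. Leaving out the cell-cycle lists thus did not keep the cell cycle out of the clusters.

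Pool 1 gave 17 of the 21 cells of the first lymphoid-primed-like cluster and pool 2 gave 18 of the 19 of the second, so their difference in Dach1 cannot be told apart from a difference between the pools. Of the unnamed clusters, pool 1 gave 22 of 28 cells of the one and pool 2 gave 26 of 28 of the other. The stem-like cells came from both pools, 23 from each. Doublets were not called.

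**Figure D3:**
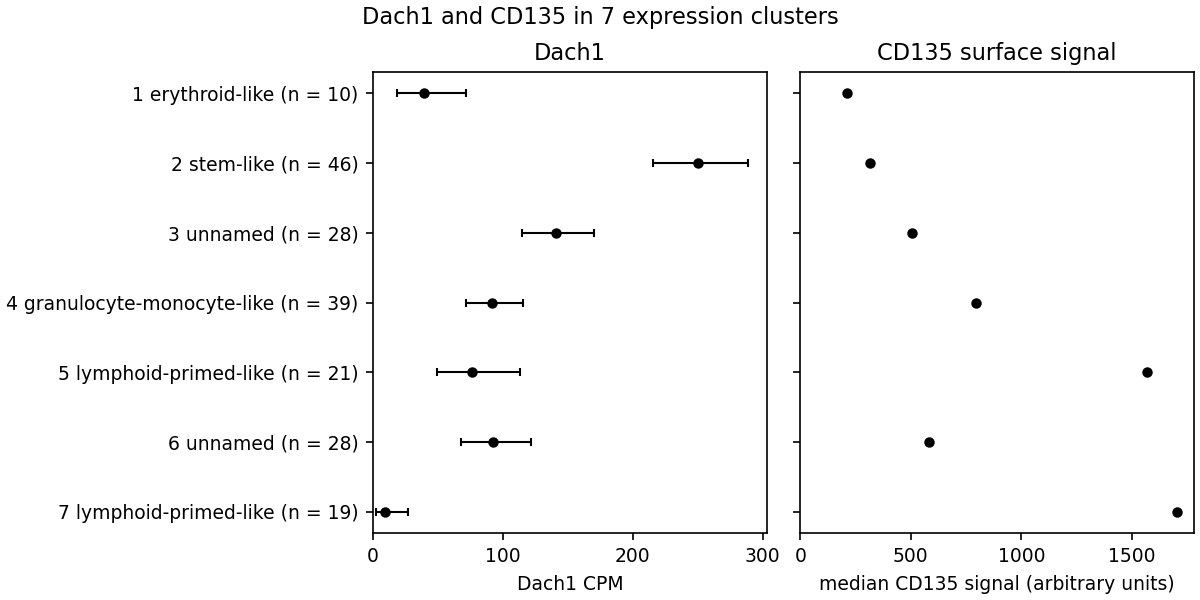
Dach1 CPM with exact 95% Poisson intervals (left) and median CD135 antibody signal in arbitrary units (right) in 7 expression clusters. The stem-like cluster has the most Dach1 (250) and the lymphoid-primed-like clusters, with the highest CD135, have 76.5 and 9.18.

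The pools differed in the level of some genes. Over 3265 genes with at least 200 UMIs, the log2 ratio of pool 1 over pool 2 lay between -0.63 and 0.59 for all but the outermost 5% on each side. Ptk2, which encodes focal adhesion kinase, had 2.65 (2.39 to 2.92), Il31ra 2.66, Lrrc58 1.47 and Mpo 1.34. Wdr92 had -1.86 (-2.08 to -1.64). Single cells enlarged other differences: without the cell that held most of the gene's UMIs, Il31ra went to 1.12, Cd74 from -2.47 to -0.84, H2-Aa from -2.07 to -0.96, H2-Ab1 from -1.94 to -1.04 and Car1 from -1.79 to -1.12. The labels describe the same sort for both pools. Their surface signals were not all alike: the CD135 median was 478.2 in pool 1 and 684.7 in pool 2, while the CD150 median was 70.8 and 68.9. Differences between the pools are therefore not all between cells of like CD135.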

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

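All alternatives here were planned before the data were examined, except the totals without Gm42418, Camk1d and Gm26384, which were chosen after seeing the data. Of 251 results, 22 answer a comparison directly. Of 3444 values under an alternative, 3 took the opposite sign of a result whose interval excluded 0, and the cause was not tested. By CD16/32, in pool 2 alone, Dach1 had a log2 ratio of -0.078 (0.65 in both pools) and G2/M genes a median of -0.42 (0.69). By Sca-1, G2/M genes had a median of 0.42 at the median split (-0.48). Among the 22, 202 values were counted as unchanged, and 31 moved beyond that in the same direction. Unchanged meant within the counting interval of the reported value, or the same rounded value for the scatter ratios. For the number of clusters a wider tolerance was used, under which 5 to 10 clusters counted as unchanged from 7. For the listed single genes and other lists 2865 stayed within the counting interval and 343 moved beyond it without changing a called sign.

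A median split compares cells closer to each other by construction. It gave log2 ratios of -1.62 for Dach1 and 1.68 for Flt3 by CD135, and medians of 1.62 for lymphoid priming by CD135, 1.18 for G2/M by CD150 and -1.35 for lymphoid priming by cKit. For the following values the cause was not tested. Pool 2 alone gave -3.47 for Dach1 by CD135, 2.02 for G2/M by CD150, -1.46 for lymphoid priming by cKit, and 1.57 for the stem cell median of the stem over the CD135-high gate. In the CD127-high cells the lymphoid priming median was 0.66 in pool 1 alone and 0.73 in pool 2 alone. Thinned cells gave 1.33 for G2/M by CD150, -1.47 for lymphoid priming by cKit and 1.63 for the stem gate's stem cell median. Equal weight per cell gave 1.23 for G2/M by CD150.

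Without the CD127-high cells the Kit ratio by cKit was 0.52 and the lymphoid priming median by cKit -1.07. Without the CD150-richest cells the Flt3 ratio by CD135 was 2.03. With list members from 50 UMIs, fewer genes by construction, the stem gate's stem cell median was 0.45; with members from 1 UMI it was 0.91. Median UMIs per cell had upper over lower forward scatter ratios of 1.44 with the stricter filter, 1.36 at the median split, 1.45 ranked over both pools, 1.80 in pool 1 and 1.36 in pool 2. For side scatter the same settings gave 1.24, 1.14, 1.19, 1.26 and 1.14, and 1.19 with no filter.

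Leaving out each of the 14 CD127-high cells kept the Il7r ratio between 7.73 and 8.25, the Dach1 ratio between -4.25 and -2.54 and the lymphoid priming median between 0.81 and 1.15. Other medians leaned on 1 cell: immediate early genes ranged from 0.13 to 1.13, B-lineage genes from 0 to 5.59, T, ILC and NK genes from 0.92 to 2.37, and, in the CD127-high cells with high CD135, G2/M genes from 0.93 to 2.25 and immediate early genes from 0.22 to 1.59. Of 188 single-gene results, 63 had a value in 1 pool outside the counting interval, and for 20 of these the pools differed by over 4-fold, a limit set after the data were seen. Other clustering settings gave 5 to 10 clusters, and the Dach1 ratio of lymphoid-primed-like over stem-like cells stayed between -2.96 and -2.06. Scaling by median ratios shifted the median gene by at most 0.10 (CD127-high cells). No paired analysis was possible because the labels give the cells no replicate numbers and no result comes from a test; the library pools were compared as separate values, and the pairs of cells of like forward scatter are matched cells, not replicates. Depth limits rare genes: Slamf1, Fcgr2b and Fcgr3 each had 20 or fewer UMIs over the classes compared.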

Other observations

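The comparison of thinned cells for Dach1 and that of CD11b and other channels for G2/M genes were tests chosen only after the results were seen. The CD127-high cells, numbered by falling CD127 signal, were not alike in their lineage genes. The second held 37 UMIs of Cd79a, 40 of Vpreb1, 37 of Igll1, 16 of Ebf1 and 7 of Rag1, genes of early B-lineage cells. Its CD135 signal was 444.8 and its cKit signal 1671, and the 177 other cells together held 5 UMIs of Cd79a and 3 of Igll1. The third held 24 UMIs of Id2, 25 of Rora, 15 of Zbtb16, 10 of Gata3 and 9 of Tcf7, genes of innate lymphoid precursors, and none of Dntt or Flt3. The first, with the highest CD127 signal, held 25 UMIs of Bcl11b, 16 of Dntt and 3 of Tcf7. These 3 cells had CD135 signals of 173.3, 444.8 and 96.9.

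The fourth to sixth cells, with CD135 signals of 1876, 2038 and 1610, held most of the Il7r UMIs (7, 11 and 14) along with Dntt (35, 74 and 97) and Rag1 (2, 4 and 1). Rag1 was seen in 5 of the 14 CD127-high cells and in 0 of the 177 others. The tenth cell differed from the rest: it had 19 UMIs of Hlf, 4 of Dach1 and 8 of Kit, none of Il7r, Dntt or Flt3, and a Sca-1 signal of 7982. Mki67 and Top2a were concentrated in 4 of the 14 cells, the first, the second, the fifth and the eighth, with 13, 38, 50 and 50 UMIs of Mki67.

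The 4 measured Y-linked genes held 944 UMIs. They were seen in all but 9 of 191 cells, where 4.13 would be without a UMI from depth alone. The fifth CD127-high cell, with 41199 gene UMIs, 74 of them Dntt and 11 Il7r, was among the 9, where its depth alone would give 10.5 Y-linked UMIs. The Y-linked genes were lower in the CD127-high cells as a group (log2 -1.17, -1.69 to -0.69), and still -0.96 (-1.48 to -0.48) over the 13 with a UMI. Whether these cells came from other animals was not tested, since the labels name none. No gene row for Xist was present.

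Dach1 was lower in the CD135 upper cells. Fewer UMIs per cell could hardly give that ratio before any test. CPM are divided by the UMIs of a class, and upper and lower cells had medians of 17227 and 18031 gene UMIs. Thinning therefore bears only on the share of cells with a UMI. At equal depth 25% of 56 upper cells had a Dach1 UMI (14.4 to 38.4) against 69.5% of 59 lower cells (56.1 to 80.8). A few lower cells rich in Dach1 are argued against as the whole reason. The 5 richest of 63 held 43.0% of its 251 UMIs there (36.8 to 49.4), under the 50% set beforehand. That interval covers counting error only, not variation from cell to cell. The richest lower cell held 33 of 160 Dach1 UMIs in pool 1 and 28 of 91 in pool 2. The ratio without the richest cells was not computed. A graded difference in Dach1 towards the CD135-high, lymphoid-primed end of LSK is a candidate explanation, found and tested on the same cells. A difference between the animals that gave cells to each class stays open, because no animal is named.

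G2/M genes were higher in the CD150 upper cells. Larger cells in that class are argued against as the whole reason: in 44 pairs of upper and lower cells of like forward scatter the G2/M median was 1.63 (1.35 to 2.07), against 1.48 without pairing. Background signal of cycling cells in the dim antibody channels stays open and could account for part of it. The G2/M median was 1.73 (1.35 to 1.94) between CD11b upper and lower cells as well (2.16 in pool 1, 0.66 in pool 2, and 0.92 without genes held by single cells), although Itgam mRNA did not differ detectably between them, and -0.74 for the CD135 channel. For Sca-1 it was -0.48, but 0.42 at the median split, and for CD16/32 it was 0.69, but 0.86 in pool 1 and -0.42 in pool 2, so neither channel decides. The difference was not confined to dim channels, however: the median was 0.56 for cKit, the brightest (0.43 in pool 1, 0.62 in pool 2), 1.59 for forward scatter (2.59 and 0.52) and 1.76 for side scatter (1.63 and 1.92). Pairing on side scatter was not tried. The CD11b and CD150 classes share cells: 30 of the 63 CD11b upper cells were CD150 upper cells, against 19 of the 64 CD11b lower cells. The CD11b value is therefore not independent of the CD150 one.

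The lymphoid-primed-like clusters were split by library pool. A library effect carried by every cell of a pool goes with the values: across 882 genes, the ratio of pool 1 over pool 2 in CD135 upper cells had a Pearson r of 0.902 (Spearman 0.723) with that in CD135 lower cells. Genes are not independent replicates, so no p-value is given. Counting error made up 4.89% and 4.82% of the variance of the ratios. Different animals in the pools could give the same value and were not tested.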
